A study of Brassica napus with 30 samples.

How the data were processed

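RNA was sequenced from seeds of oilseed rape (Brassica napus), an allotetraploid that carries an A and a C subgenome. The 2 genotypes, JY1605 and JY1621, were sampled as dry seeds and after 8 h and 36 h of imbibition at 25 °C or 8 °C. That gives 10 groups of 3 libraries, 30 in all. The labels call the libraries of a group biological replicates, and per the labels' protocols each RNA sample came from 100 seeds. Whether the replicates of a genotype came from separate seed lots is not given in the sources used here. Sampling time and time of day went together: dry seeds were taken at zeitgeber time 0, the 8 h seeds at 8 and the 36 h seeds at 12, so that a change between sampling times is also a change between times of day. Comparisons of temperature or genotype at one sampling time are free of this.

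The values are raw gene counts deposited by the authors as one table of 100919 gene models. Per the submitters' processing notes, HISAT2 2.2.1, featureCounts 2.0.6 and DESeq2 1.42.0 were used; the parameters of the alignment and counting, the strand setting and the genome build are not given in the sources used here. The values were checked to be whole numbers whose totals differ between libraries. How reads that match both homoeologous copies of a gene were counted is not known, so a count of one copy can hold reads of the other. Total counts ran from 14250480 to 78251632 per library. The deepest library was replicate 1 of JY1621 at 36 h and 25 °C, and the next held 35172867. Of the gene models, 14800 had no count in any library.

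The gene IDs carry the chromosome (A01 to A10, C01 to C09 or an unplaced scaffold) and an order along it, and these were read from the IDs. Of the IDs, 0 matched the RefSeq gene table used here, which describes another assembly with 123214 genes. No gene names or functions could therefore be attached. The 31 gene lists fixed before the data were examined were void and were not tested, and the rule for named genes fell back on its last clause: at 36 h, among gene models called in the same direction in both genotypes with a mean of at least 8 CPM over the 12 libraries, the 2 with the largest smaller-of-2 fold change in each direction, given by ID.

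Differences were tested with edgeR 4.0.16 (quasi-likelihood F-test with robust estimation, TMM factors, R 4.3.3) in one fit of all 30 libraries with 1 mean per group, so that all groups shared one estimate of the spread. Gene models were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 57945. A gene model was called at an adjusted p (Benjamini-Hochberg over all tested) under 0.05 with an absolute log2 fold change of at least 1. The 19 comparisons were 8 °C against 25 °C at each time in each genotype, the difference of that effect between genotypes at each time, JY1621 against JY1605 in each of 5 conditions, and imbibed against dry seeds. Standard errors of log2 fold changes were taken from the fold change and its F statistic. The functions were tested on simulated counts for the comparison of temperatures at 36 h in JY1605 with 53203 gene models. Of 100 seeded at a log2 fold change of 1.5, 95% were recovered, of 100 seeded at 3, 100% were, and 3 others were called. The seeded models had a mean above 1 CPM and as many rose as fell. All other models kept one mean level in all libraries. The simulation thus does not show how calls fare where most gene models change or the composition of libraries differs.

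The position of a library along germination at 25 °C was its projection, in log2 CPM with a prior count of 2, on the difference between dry and 36 h 25 °C seeds of the other genotype, over the gene models called there, scaled to 0 at the mean of dry and 1 at the mean of 36 h 25 °C libraries of its own genotype. Positions, and shares of counts, were compared by exact two-sided permutation tests. With 3 libraries against 3 there are 10 splits, and the smallest p is 0.1, so no such test can pass 0.05. Gene models called between temperatures at 36 h in one genotype were placed by the call of 36 h 8 °C against dry seeds in the other genotype, so that no library entered both. For a gene with no count over the 3 libraries of a group, a fold is a lower bound against 3 counts over the group, from counts summed over libraries. With 1 to 3 counts it is a ratio with its exact 95% binomial interval. Such bounds cover counting error only, since reads are not independent molecules.

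Replicates were compared first. Pearson correlations of log2 CPM within groups ran from 0.972 to 0.99, each of the 30 libraries was closest to a library of its own group, and chi-square per degree of freedom between libraries of a group was 2.71 to 7.18, so no pair agreed within sampling noise. The alternatives planned before the data were examined were DESeq2's median-of-ratios factors within edgeR, library size scaling without composition factors, no low-count filter, the DESeq2 1.42.0 Wald test, fits of only the groups compared, the replicate number as a block, no fold minimum, other settings of the axis, and each library left out in turn. Alternatives without the co-moving gene models, and without chromosome windows that share a genotype difference, were chosen after seeing the data. Co-moving gene models are 2514 tested models whose course over the 10 group means lay within 0.5 (root mean square, log2) of the median course of the models on unplaced scaffolds, and that lay on a scaffold or among 25 neighbours of which at least 50% matched. Windows are 50 neighbouring tested models, taken to share a genotype difference where the window's median was at least 0.7 (log2) in one direction in all 5 conditions.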

Results

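The deposited table holds gene counts of 30 seed libraries of 2 oilseed rape genotypes, JY1605 and JY1621. Each genotype was sampled as dry seeds and after 8 h and 36 h of imbibition at 25 °C or 8 °C, with 3 libraries per group. Imbibition is the uptake of water that starts germination, and 8 °C is a low temperature for this crop. Total counts ran from 14250480 to 78251632 per library. The first 3 principal components held 39%, 23.6% and 19.3% of the variance, and each library lay closest to another of its own group. Gene models are given by ID or by chromosome only, because no names could be attached to them.

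After 8 h, the share of counts taken by a library's most abundant gene models was nearer to dry seeds at 8 °C than at 25 °C. In dry seeds the 100 most abundant gene models took 29.1% ± 0.419 of the counts in JY1605 and 28.1% ± 0.717 in JY1621 (SD, n = 3). After 8 h at 8 °C they took 25.1% ± 0.244 and 23.4% ± 0.763, and after 8 h at 25 °C 7.59% ± 0.218 and 8.76% ± 0.286. The 8 °C and 25 °C libraries did not overlap in either genotype (exact two-sided permutation test, p = 0.1, the smallest possible). The number of gene models at 1 CPM or more was 36533 ± 359 in dry JY1605 seeds, 37963 ± 178 after 8 h at 8 °C and 41916 ± 125 after 8 h at 25 °C. In JY1621 it was 37707 ± 256, 40095 ± 260 and 41321 ± 386, so that the 8 °C libraries lay nearer to 25 °C than to dry seeds by this measure.

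Cold against warm imbibition at 8 h asks how far low temperature alters early germination. In JY1605, 11586 gene models were higher and 12336 lower at 8 °C than at 25 °C, and in JY1621 9788 were higher and 9505 lower. Of these, 6260 were higher and 6866 lower in both genotypes, where independent lists would share 1957 and 2024, and 156 went opposite ways. The 2 sets of log2 fold changes correlated across gene models at 0.673 (Pearson), a description only, since genes are not independent replicates. In JY1605, 2460 of the higher calls were co-moving gene models, most of which lie in blocks on A01, A05, A06 and A09 or on unplaced scaffolds, against 89 in JY1621. The balance of directions depends on the scaling. With library size scaling only, 6440 were higher and 20833 lower in JY1605, and 6841 higher and 13652 lower in JY1621, the median of all gene models moving by -0.563 and -0.244 (log2). Both genotypes then shared 3622 higher and 11467 lower calls, against 760 and 4908 for independent lists.

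**Figure D1:**
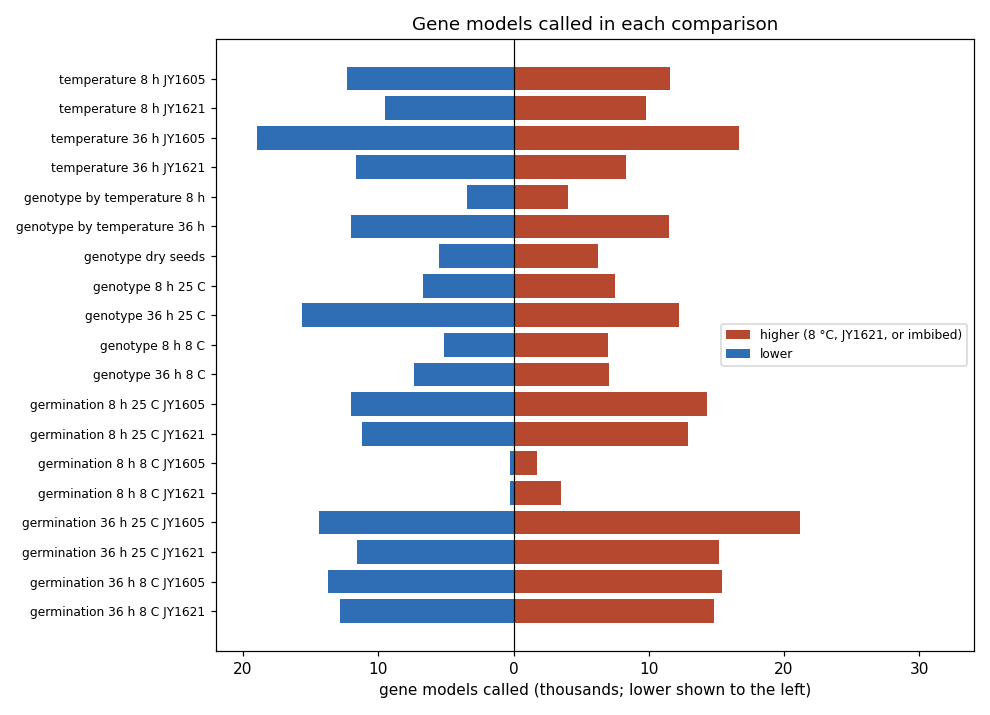
Gene models called in each of the 19 comparisons, with those higher at 8 °C, in JY1621 or in imbibed seeds to the right and those lower to the left; for genotype by temperature, right means a larger log2 effect of 8 °C in JY1621. The 36 h comparison of temperatures in JY1605 reached 35593 calls, and 8 h at 8 °C against dry seeds in JY1605 1973.

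At 36 h the temperatures separated JY1605 more than JY1621. In JY1605, 16655 gene models were higher and 18938 lower at 8 °C, 61.4% of those tested, and in JY1621 8315 were higher and 11655 lower, 34.5%. Both genotypes shared 5821 higher and 9211 lower calls, against 2390 and 3809 for independent lists, and 693 calls were opposite. The fold changes correlated at 0.702 across gene models between genotypes, but at 0.0438 in JY1605 and -0.0514 in JY1621 between 8 h and 36 h. Of the gene models called at both times in JY1605, 4932 were higher at 8 °C at both, 3122 lower at both and 7352 opposite. Independent lists would give 3330, 4032 and 7332, so with all gene models the opposite calls were close to that number. With library size scaling only they were 7800, against 7850. In JY1621 these were 1297, 1572 and 4833, where independent lists would give 1405, 1912 and 3333. Without the co-moving gene models, 2502 were higher at both in JY1605, 3108 lower at both and 7347 opposite. Independent lists would then give 2333, 4208 and 6266, so the opposite calls exceeded that number and those lower at both fell short. The fold changes then correlated at -0.00589. Co-moving gene models made up 2472 of the higher calls in JY1605 and 46 in JY1621. Library size scaling moved the median of all gene models by -0.102 (log2) in JY1605.

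The gene models with the largest shared changes at 36 h show both kinds of response. BnaC02G0128600ZS, on C02, stood at 22.4 ± 0.531 CPM at 8 °C and 0.0766 ± 0.0674 at 25 °C in JY1605, and at 16 ± 2.23 and 0.599 ± 0.18 CPM in JY1621 (SD, n = 3). Its dry-seed levels were 7.8 ± 2.44 and 15.4 ± 2.02 CPM. The log2 fold change was 7.99 ± 0.364 (SE, edgeR adjusted p = 2.49e-18) in JY1605, where 25 °C rests on 8 counts, and 4.6 ± 0.266 in JY1621 (edgeR adjusted p = 2.75e-15). Leaving out 1 library gave 7.52 to 8.59 in JY1605, the highest without replicate 2 at 25 °C. BnaA03G0109400ZS, on A03, rose from 11.4 ± 1.44 CPM in dry JY1605 seeds to 70.7 ± 2.97 at 36 h and 8 °C, and from 4.24 ± 0.806 to 43.3 ± 1.98 in JY1621, while it stood at 1.78 ± 0.235 and 1.83 ± 0.387 CPM at 36 h and 25 °C. Its temperature effect was 5.31 ± 0.164 in JY1605 (SE, edgeR adjusted p = 2.6e-27) and 4.53 ± 0.162 in JY1621 (edgeR adjusted p = 2.05e-24). Among gene models lower at 8 °C, BnaC01G0170900ZS, on C01, held 60545 counts over the 3 libraries of JY1605 at 36 h and 25 °C, 641 ± 102.7 CPM, and 2 counts at 8 °C, a ratio of 29700 with a 95% interval of 8210 to 245000, and 18300 without replicate 1 at 8 °C. In JY1621 it held 38.1 ± 23.5 CPM at 25 °C, 25.6 CPM by summed counts, and no count at 8 °C, at least 786-fold below the summed level. That bound was 1530 without replicate 1 at 25 °C, and 447 and 493 without replicates 1 and 2 at 8 °C. With all libraries, the exact 95% binomial interval started at 639. BnaC09G0444000ZS, on C09, had no count at 36 h and 8 °C in either genotype. At 25 °C it held 28.1 ± 6.53 CPM in JY1605 and 8.55 ± 0.818 CPM in JY1621, by summed counts 27.7 and 8.89 CPM. The 8 °C level was at least 868-fold below the summed level in JY1605 and at least 273-fold in JY1621. Without replicate 1 at 8 °C these bounds were 536 and 155, and without replicate 2 at 8 °C that of JY1621 was 171. With all libraries, the exact 95% binomial intervals of this gene model started at 705 in JY1605 and 222 in JY1621.

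The effect of temperature itself differed between the genotypes. At 8 h the difference of the effects was called for 7443 gene models, 4016 with a higher and 3427 with a lower log2 effect in JY1621. At 36 h it was called for 23539, 11487 and 12052. Co-moving gene models were 1470 of the lower calls at 8 h, where leaving them out before adjustment gave 1929 lower calls, and 2249 at 36 h. With library size scaling only, the 8 h calls became 6481 higher and 1643 lower, with a shift of the median of 0.25 (log2), against 0.11 at 36 h. The 36 h calls became 12791 higher and 10945 lower with that scaling, and 11458 and 9789 without co-moving models, so their balance turned.

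Along the course of germination at 25 °C, JY1605 seeds after 36 h at 8 °C lay where they lay after 8 h at 25 °C, and JY1621 seeds lay further along, with no overlap of libraries. On the scale from dry seeds (0) to 36 h at 25 °C (1), JY1605 stood at 0.528 ± 0.0063 after 36 h at 8 °C and at 0.528 ± 0.0103 after 8 h at 25 °C (SD, n = 3; exact two-sided permutation test, p = 1). JY1621 stood at 0.58 ± 0.0145 and 0.482 ± 0.0208 (exact two-sided permutation test, p = 0.1, the smallest possible). After 8 h at 8 °C the positions were 0.08 ± 0.0022 and 0.118 ± 0.0278. Over the 11 tests of positions the adjusted p was at least 0.11. Each scale is relative to the genotype's own end points, which were not equally far apart. On the scale set by JY1605's end points, JY1621 reached 0.578 ± 0.0263 at 36 h and 25 °C, and on JY1621's, JY1605 reached 1.18 ± 0.0224. The values depend on whose gene models define the axis: with the own genotype's axis, 36 h at 8 °C lay at 0.335 in JY1605 and 0.704 in JY1621, 8 h at 25 °C at 0.342 and 0.655, and 8 h at 8 °C at 0.0593 and 0.177. Those in JY1605 at 36 h and 8 °C and at 8 h and 25 °C, and that in JY1621 at 8 h and 8 °C, moved by over 1.5 times.

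**Figure D2:**
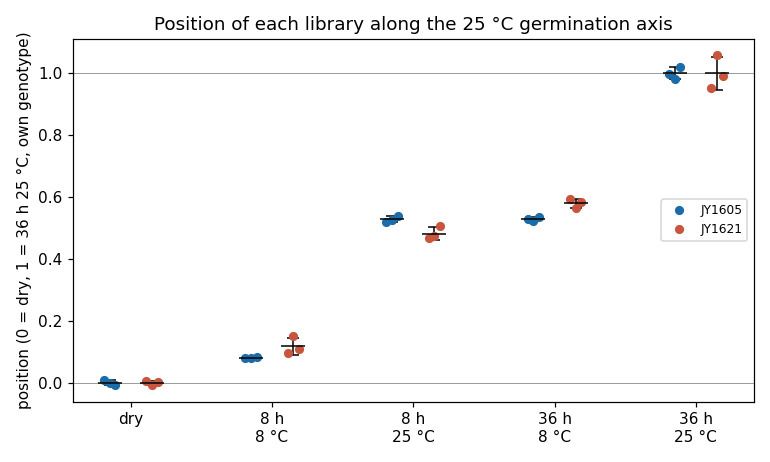
Position of each library along the 25 °C germination axis, on a scale from 0 (mean of dry) to 1 (mean of 36 h at 25 °C of the same genotype), by stage; points are the 3 libraries of a group, bars the mean and SD. The 36 h 8 °C libraries of JY1605 average 0.528, as do those of 8 h at 25 °C.

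Counted by gene model, 36 h at 8 °C differed from 8 h at 25 °C by 8092 calls in JY1605 and 7759 in JY1621. Against dry seeds there were 29096 and 27601 calls, against 8 h at 8 °C 27147 and 23193, and against 36 h at 25 °C 35593 and 19970. The stages also differ in time of day.

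Gene models higher at 8 °C at 36 h were not only ones left at their dry-seed level. Of the 8315 higher in JY1621, 56.9% were above dry seeds in JY1605 at 36 h and 8 °C, 7.54% below and 35.6% not called. Among all tested gene models 26.6% were above and 23.7% below in JY1605, and 25.5% and 22.1% in JY1621. Of the 16655 higher in JY1605, 35.6% were above dry seeds in JY1621, 18.2% below and 46.2% not called. In both genotypes 5821 gene models were called higher and 9211 lower at 8 °C. The other members of each set were placed in a genotype that lacked that call. Of those lower at 8 °C, 27.3% of the JY1605 set and 36.4% of the JY1621 set were below dry seeds in the other genotype, and 15.9% and 12.7% above. These shares are counts with no test of their own, and library size scaling changed 3032 below-dry models of the JY1605 set to 1909 and 627 of the JY1621 set to 415. That scaling moved all tested gene models, to 38.1% above and 14.5% below dry seeds in JY1605 and 36% and 14.6% in JY1621. The models lower at 8 °C then stood at 23.7% above and 18.2% below for the JY1605 set and 19.3% and 24.7% for the JY1621 set, against that background again fewer above and more below.

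Imbibition changed 41.6% to 61.4% of the tested gene models at 25 °C, and after 8 h at 8 °C 3.4% in JY1605 and 6.49% in JY1621. Against dry seeds, 8 h at 25 °C gave 14287 higher and 12032 lower calls in JY1605 and 12861 and 11221 in JY1621. After 8 h at 8 °C, 1728 were higher and 245 lower in JY1605, and 3483 and 278 in JY1621. The lean to higher calls at this stage depends on the fold minimum: without it there were 5046 and 2518, and 6310 and 4818. With library size scaling only there were 2199 and 178, and 4761 and 124. With fits of only the groups compared, the lower calls were 139 in JY1605 and 123 in JY1621. After 36 h at 25 °C, 21202 were higher and 14354 lower in JY1605, and 15187 and 11599 in JY1621. After 36 h at 8 °C, 15392 and 13704 were called in JY1605, and 14787 and 12814 in JY1621. With library size scaling only, higher against lower calls became 23673 and 6251 at 8 h and 25 °C in JY1605, 19317 and 6549 in JY1621, 28303 and 10170 at 36 h and 25 °C in JY1605, 21958 and 6765 in JY1621, and, at 36 h and 8 °C, 22081 and 8394 in JY1605 and 20840 and 8461 in JY1621. The median of all gene models then moved by 0.487 to 0.663 (log2), and by 0.168 at 8 h and 8 °C in JY1621.

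Of the 2514 co-moving gene models, 2373 were called lower than in dry JY1605 seeds after 8 h at 25 °C, 2514 after 36 h at 25 °C and 2402 after 36 h at 8 °C, and in JY1621 333, 1852 and 362. They were chosen for a shared course, so that their moving together follows from the choice. They held 1.71% ± 0.0248 of counts in dry JY1605 seeds, 0.835% ± 0.141 after 8 h at 25 °C and 0.181% ± 0.0175 after 36 h (SD, n = 3). In JY1621 they held 1.87% ± 0.0732, 1.7% ± 0.0546 and 1.17% ± 0.0793. After 8 h at 8 °C they held 1.69% ± 0.027 in JY1605 and 1.89% ± 0.0827 in JY1621, with median log2 changes from dry seeds of -0.0843 and -0.172. After 36 h at 8 °C they held 0.784% ± 0.243 in JY1605 and 1.67% ± 0.232 in JY1621, where the libraries, at 1.41% to 1.84%, overlapped those of dry seeds, at 1.79% to 1.92%. The median log2 change was then -1.59 in JY1605 and -0.686 in JY1621. The median log2 change from dry seeds to 36 h at 25 °C was -3.8 in JY1605, with quartiles of -4.2 and -3.49, and -1.21 in JY1621, with quartiles of -1.45 and -0.991. These changes are scaled for composition and the shares are not: with that scaling the summed level in JY1621 was 23381 ± 1020 CPM in dry seeds, 14816 ± 572 after 8 h and 10377 ± 431 after 36 h at 25 °C. On A05 they were 766 of 874 neighbouring tested models, on A09 562 of 611, on A06 146 of 185 and on A01 105 of 120, and 877 lay on unplaced scaffolds. The others were 37 on C08, 13 on C03, 6 on C07 and 2 on C06.

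**Figure D3:**
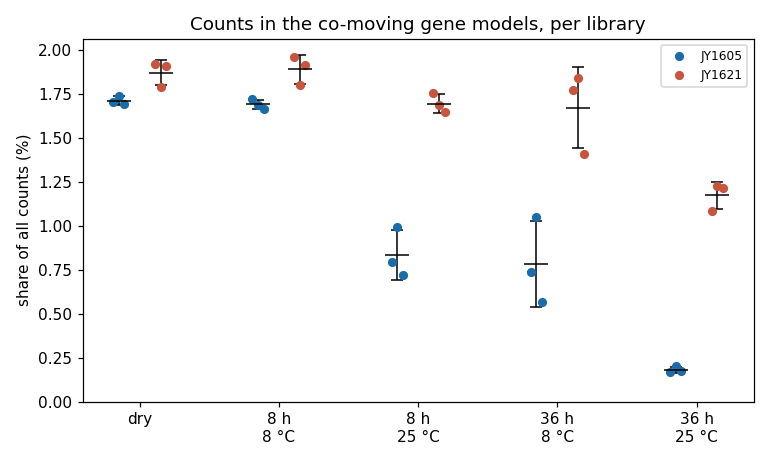
Share of all counts in the 2514 co-moving gene models, in percent, per library and stage; points are libraries, bars the mean and SD of 3. JY1605 falls from 1.71% in dry seeds to 0.181% at 36 h and 25 °C, JY1621 from 1.87% to 1.17%.

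The genotypes differed in every condition, most of all at 36 h and 25 °C. JY1621 was higher for 6258 and lower for 5517 gene models in dry seeds, 7475 and 6711 at 8 h and 25 °C, 12240 and 15656 at 36 h and 25 °C, 7009 and 5149 at 8 h and 8 °C, and 7037 and 7389 at 36 h and 8 °C. In all 5 conditions 1771 gene models were higher and 2033 lower in JY1621, and 37248 were called in at least 1. Fold changes between genotypes correlated across gene models at 0.416 to 0.807 between conditions, which share no library. Of the calls higher in JY1621, 2513 at 36 h and 25 °C, 1683 at 8 h and 25 °C and 1598 at 36 h and 8 °C were co-moving gene models. Leaving these out before adjustment turned the balance at 8 h and 25 °C, to 5779 higher and 6693 lower. With library size scaling only, 8 h at 8 °C gave 8912 higher and 4086 lower calls, the median of all gene models moving by 0.191 (log2). That scaling gave 6832 higher and 7145 lower calls at 8 h and 25 °C, and 7563 and 7024 at 36 h and 8 °C, so the balance turned in both.

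Some stretches of chromosome differed between the genotypes in all 5 conditions. Over the first 500 tested gene models of C02, the median difference was -3.45 (log2; -3.2 with groups under 3 counts set to 3), and 345 were lower in JY1621 in all 5 conditions. At the start of A02, 50 neighbouring models had a median of 3.58 (2.71 with that floor) and 300 others a median of 1. On C01, 200 models had a median of 3.79 (3.24 with that floor) and 150 of -2.76 (-2.5), and on A01 100 models one of -3.76 (-3.34). Windows that share such a difference formed 15 regions and held 3.31% of the tested models. Other regions lay on A09 (medians of -3.64, 1.1 and -2.2), C09 (-2.32 and 1.3) and C04 (1.93). The rest were on A01 (-0.983 and 0.873) and C01 (1.3).

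**Figure D4:**
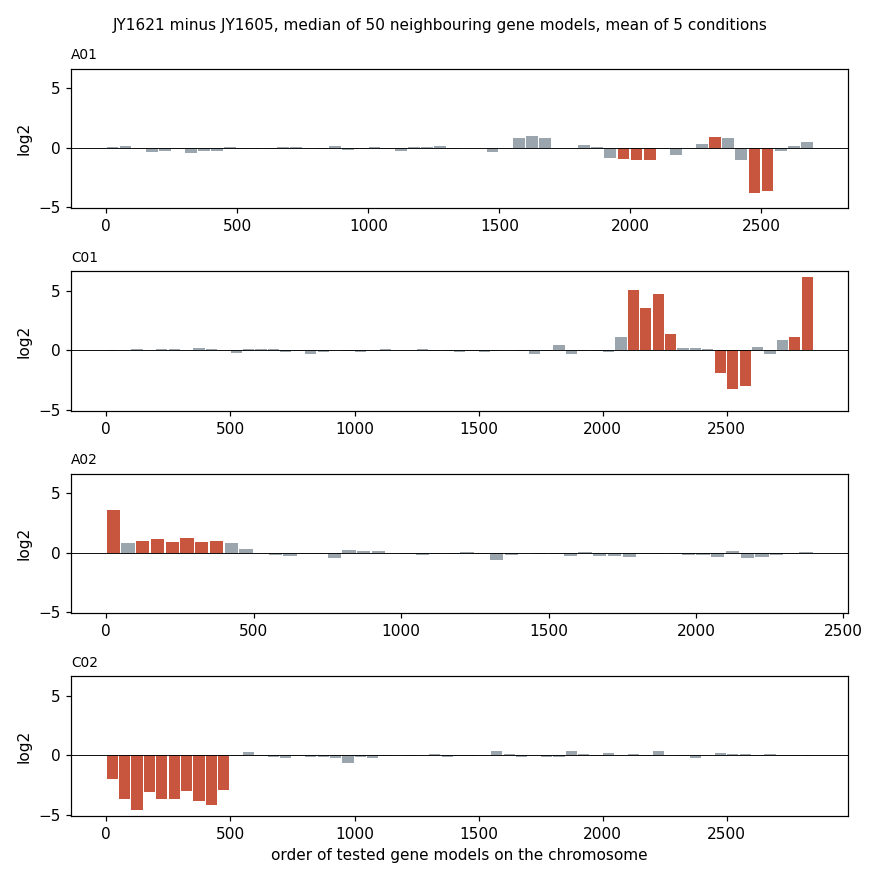
Difference of JY1621 from JY1605 (log2) along A01, C01, A02 and C02, each bar the median of 50 neighbouring tested gene models, averaged over the 5 conditions; red bars passed 0.7 in one direction in all 5. The first 500 models of C02 lie low and the start of A02 lies high. A09, C04 and C09 also held such windows and are not drawn.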

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

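The effect of temperature differed between the genotypes for 7443 gene models at 8 h and for 23539 at 36 h, by the test of the difference itself. For BnaC02G0128600ZS the effect at 36 h was smaller in JY1621 than in JY1605 by -3.39 ± 0.62 (log2, SE; edgeR adjusted p = 2.88e-05), and for BnaA03G0109400ZS by -0.784 ± 0.237 (edgeR adjusted p = 0.00456), which is under the fold minimum. Both were chosen as higher at 8 °C in each genotype, so that their direction in 3 of 3 libraries of each follows from the choice. With 1 library left out, the effect for BnaC02G0128600ZS in JY1605 ranged from 7.52 to 8.59, the highest without replicate 2 at 25 °C.

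Regrouping the libraries between genotypes within each temperature gave 40 splits, the real one included. At 36 h, 1 of 40, the real one with 23539 calls, was as large, and the highest other gave 22897. At 8 h, 5 of 40 gave as many as the 7443 real calls, with up to 13420, so chance is not excluded by this count. The splits point to a structure of the samples: the 9 drawn splits at each time that kept the genotypes apart at one temperature gave up to 13420 calls at 8 h and 22897 at 36 h, and the 30 that mixed them at both gave 0. Such a half-mixed split holds the genotype difference of one temperature, and a split mixed at both puts that difference into the spread. Neither kind is a null for a difference of effects alone, so the splits cannot decide on chance at either time.

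Why the difference is so wide at 36 h may lie in how far each genotype had come at 25 °C. If JY1605 was further along than JY1621, over 80% of the 23539 calls should have the sign of JY1621's own change from 8 h to 36 h at 25 °C, and at most 50% if not. The share was 73.4%, between those bounds, although the libraries shared by both contrasts push it down, so that this explanation stays open. It was 83.8% for the 7594 calls that were also called between 8 h and 36 h in JY1621, and 70.6% without the co-moving gene models. Neither of these shares was planned. The test of scaling cannot decide, since a total can hold while calls trade direction. Without composition factors there were 1.01 times as many calls, with 12791 higher and 10945 lower against 11487 and 12052. A genotype difference in the response to cold itself stays among the open explanations and was not tested apart from progress at 25 °C.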

How the results depend on the processing

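No total of higher and lower calls in the 19 comparisons moved by over 1.5 times with DESeq2's factors, library size scaling, no low-count filter, the DESeq2 Wald test, fits of only the groups compared, the co-moving gene models left out, or any library left out, and none did in the 5 genotype comparisons without the windows. Counts of a single direction did move more: with library size scaling in some of the comparisons, where its counts are given beside the main ones, with fits of only the groups compared for lower calls at 8 h and 8 °C against dry seeds (245 to 139 in JY1605 and 278 to 123 in JY1621), and without co-moving models for the lower differences of effects at 8 h (3427 to 1929). Overlaps of temperature calls moved that far with library size scaling at 8 h between genotypes, to 3622 higher and 11467 lower in both, and between times in JY1605, to 2914 and 5762, and without co-moving models to 2502 higher at both times. Independent lists would share 760 and 4908 in the first case, 1741 and 7172 in the next and 2333 in the last. The alternatives without co-moving models, without windows and for the overlaps were chosen after seeing the data. The 4 gene models given by ID kept direction and call under every alternative run. Gene list alternatives were not run, since the lists were void. Few or no counts at 36 h and 8 °C limit the folds that can be given for BnaC01G0170900ZS and BnaC09G0444000ZS. The library of lowest depth, with 14250480 counts, was of dry JY1605 seeds and enters none of these folds.

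Without the fold minimum, calls rose between temperatures to 37045 at 8 h in JY1605, 34142 at 8 h in JY1621 and 37253 at 36 h in JY1621, and for the difference of effects at 8 h to 15242. Between genotypes they rose to 23835 in dry seeds, 29053 and 43925 at 8 h and 36 h at 25 °C, and 24636 and 28962 at 8 h and 36 h at 8 °C. Against dry seeds they rose to 37689 at 8 h and 40564 at 36 h at 25 °C in JY1621, and at 8 h and 8 °C to 7564 in JY1605 and 11128 in JY1621. The alternative drops a criterion, which is the cause.

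Of the 6 axis positions, 5 or 6 moved by more than 1 SD with other axis gene models, scaling, prior count or axis genotype, 1 without co-moving models, and 10 of 180 values with a library left out. The cause was not tested. For JY1605 at 8 h 25 °C, 8 h 8 °C and 36 h 8 °C they were 0.46, 0.0719 and 0.469 with axis gene models of at least 3 (log2), 0.57, 0.0906 and 0.552 with library size scaling only, 0.503, 0.0852 and 0.505 with a prior count of 0.5, and 0.342, 0.0593 and 0.335 on the genotype's own axis. For JY1621 they were 0.449 and 0.553 (8 h 25 °C and 36 h 8 °C) with the stricter gene models, 0.523, 0.146 and 0.605 with library size scaling only, 0.456 and 0.561 (8 h 25 °C and 36 h 8 °C) with the other prior, and 0.655, 0.177 and 0.704 on its own axis. Without co-moving models, JY1605 at 8 h 8 °C lay at 0.0832. With each library left out, JY1605 lay at 0.514 to 0.542, 0.0771 to 0.0839 and 0.513 to 0.544, and JY1621 at 36 h 8 °C at 0.568 to 0.597.

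Gene models placed against dry seeds also moved. Of those higher at 8 °C in JY1605, 11087 were above and 6991 below dry seeds in JY1621 without the fold minimum, and 1909 below with library size scaling only. Of those lower in JY1605, 6096 were above and 9310 below without the minimum, and 4727 above and 3633 below with that scaling, which moved all tested models from 25.5% above and 22.1% below to 36% and 14.6%. Of those higher in JY1621, 10781 were above and 3762 below dry seeds in JY1605 without the minimum, and 415 below with the scaling. Of those lower in JY1621, 4043 were above and 9367 below without the minimum, and 2227 above with the scaling.

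With the replicate block, the counts of calls ran from 1946 at 8 h and 8 °C against dry seeds in JY1605 to 35541 between temperatures at 36 h in JY1605, and none moved by over 1.5 times. Whether the numbers pair the samples is not settled. Of 135 pairs of libraries with the same number in different groups, 1 had deviations from the group means that correlated above 0.1. Of 270 pairs with different numbers, 0 did. In deviation, 14 of 30 libraries were closest to one of their own number, and how many would be so by chance was not computed.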

Other observations

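Of the tests in this part, those of the closest stage, of the repeated sequence, of genomic DNA and all of those on the chromosome stretches were chosen after their patterns had been seen; the germination-progress test of the co-moving gene models and the splits were not.

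The A subgenome's share of the counts on chromosomes was higher in JY1605 where seeds were dry or had been 8 h at 8 °C. In dry seeds it was 51.1% ± 0.0989 in JY1605 and 49.2% ± 0.124 in JY1621 (SD, n = 3), and after 8 h at 8 °C 50.7% ± 0.23 and 49.2% ± 0.287. After 8 h at 25 °C it was 48.7% ± 0.0831 and 49% ± 0.0576. Each of these 3 differences had p = 0.1 in an exact two-sided permutation test, the smallest possible, and 0.129 after adjustment over the 9 comparisons of this share. In dry seeds the single most abundant gene model took 2.39% of the counts in JY1605 and 1.41% in JY1621, so a few models can weigh on this share. Whether they made the difference was not tested. The number of gene models at 1 CPM or more rose to 45096 ± 63.1 in JY1605 and 42520 ± 177 in JY1621 at 36 h and 25 °C, and was 41198 ± 77.5 and 41190 ± 55 at 36 h and 8 °C (exact two-sided permutation test between genotypes at 8 °C, p = 0.9).

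Seeds after 36 h at 8 °C may resemble those after 8 h at 25 °C more than either end of the 25 °C course. They differed from them by 8092 calls in JY1605 and 7759 in JY1621, fewer than from dry seeds (29096 and 27601) or from 36 h at 25 °C (35593 and 19970). The closeness was seen before it was tested, and time of day differs between these stages. The highest of the other 9 splits gave 1 call in JY1605 and 0 in JY1621, but these splits mix the stages and put their difference into the spread. With 10 splits, the share of splits as large, 1 of 10 here, cannot fall under 0.05.

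The co-moving gene models moved as one. Deviations of libraries from their group means correlated between the A05 and A09 blocks at r = 0.9828 over 30 libraries (rho = 0.947; permutation within groups, p = 1e-05 for each, the smallest possible), and at 0.957 without the 2 libraries farthest from the median. In dry JY1605 seeds, 65% of the 98405 other models in the table were under 1 CPM, against a median of 4.44 CPM for the co-moving models. Those others include models that the low-count filter removed, while the co-moving models had passed it and were chosen by their course. These levels therefore cannot decide on genomic DNA spread evenly over gene models. The change of weakly counted models elsewhere cannot decide on genomic DNA either. They rose by a median of 2 (log2) in JY1605 where the blocks fell by 3.8, a ratio of -0.526. The low-count filter, however, had kept only those that were higher in some group. One repeated sequence, with its reads counted over many models, is a candidate explanation that the correlation allows, though regulation shared by the blocks would give it too. Replicates that differ in germination progress stay open as well: 329 outside models with the same fall deviated with the blocks with a slope of 0.45 (0.416 to 0.52 with any 1 group left out), which is not under the bound of 0.5 by more than that range. The deviations of these outside models correlated with those of the blocks at 0.822, so deviating together was not particular to the blocks.

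Gene models called between genotypes in all 5 conditions were not placed at random along the chromosomes. They formed 1091 neighbouring pairs, against at most 289 in 1000 random placements. With both the stretches and the co-moving gene models left out there were 506, against at most 205, so the excess was not confined to the stretches. The stretches were defined by neighbours that share a difference, so the count is no separate test of them. A C02 region of JY1621 too diverged to be aligned stays open: the A02 region was higher by a median of 1 (log2), but it was chosen by that difference, and reads of a diverged copy could have been counted on A02. That the C02 region was exchanged for its A02 counterpart may be so but stays undecided too. The summed CPM of both regions was lower in JY1621 by a mean log2 ratio of -0.215 (-0.272 to -0.17 over the 5 conditions), too near the bound of 0.25 set for it. The sum depends on which A02 models count as the region, a choice made after a first value was seen: it was -2.31 with only the first 50, the first definition tried, -0.215 with 400 and -0.121 with 500.

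For the comparisons of 3 libraries against 3, the 10 splits are too few for a share under 0.05. In each, the real split alone, 1 of 10, reached its count. Every other split mixes the groups compared and so puts any difference between them into the spread. The few calls of those splits therefore do not measure how many calls chance would give. Between temperatures the real split and the highest other gave 23922 and 0 calls at 8 h in JY1605, 19293 and 2 at 8 h in JY1621, 35593 and 4 at 36 h in JY1605, and 19970 and 0 at 36 h in JY1621. Between genotypes they gave 11775 and 5 in dry seeds, 14186 and 0 at 8 h and 25 °C, 27896 and 2 at 36 h and 25 °C, 12158 and 0 at 8 h and 8 °C, and 14426 and 6 at 36 h and 8 °C. Against dry seeds, JY1605 gave 26319 and 1 at 8 h and 25 °C, 1973 and 2 at 8 h and 8 °C, 35556 and 0 at 36 h and 25 °C, and 29096 and 1 at 36 h and 8 °C. JY1621 gave 24082 and 2, 3761 and 13, 26786 and 1, and 27601 and 1.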
